A study of Rattus norvegicus with 183 samples.

How the data were processed

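PolyA RNA was sequenced from the posterior ventral tegmental area, a midbrain region that holds dopamine neurons, of outbred heterogeneous stock rats. The series describes 183 samples from this region and 152 of them have a column of values. The other 31 carry a label saying that they were removed, and they were not used here. The labels name 1 tissue and give no treatment, sex, age or sequencing batch. Apart from notes on relabelling, the only label that divides the animals is the format of the identifier in the sample title. A decimal identifier was given to 63 libraries, a hexadecimal one to 88 and another form to 1. Per the labels, 5 of the 152 libraries were relabelled and 12 were recovered from an unknown label.

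The deposited values are log2-transformed, as the name of the deposited table says. Per the labels' processing notes, the authors used kallisto 0.48, which assigns reads to transcripts by pseudoalignment and returns an estimated count. The deposited log2 values have the properties of log2(estimated count + 1): 0 stays 0, the back-transformed totals lie between 15.2 and 57.2 M (1e6) per library, and 55.7% of the back-transformed values below 100 lie within 0.001 of a whole number. The unit was therefore taken from the values, since no label states it. The genome build is not given in the sources used here. Each gene has a chromosome and 1 position in the file, and 99.8% of these positions are an end of the gene of the same symbol in the reference gene table (GRCr8). That table was used for gene type, gene span and neighbours, and 38272 of the 38354 genes have a symbol in it. The file has 22 chromosome names (the autosomes, X and Y), so the 13 listed genes of the mitochondrial genome have no value.

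Because the largest total is 3.77 times the smallest, more than the 2% within which totals had to lie for the values to be used unchanged, the values were back-transformed and expressed as counts per 1e6 counts of the library (CPM), then as log2(CPM + 1). Genes entered where their mean over the 152 libraries was at least 1 on this scale, which left 15536 genes of the 34551 with any count. The median library held 24.3 M estimated counts (quartiles 20.8 and 28.1 M) and 24023.5 genes with at least 1 count. The median was 26.5 M for decimal and 22.9 M for hexadecimal identifiers. At these depths 1 CPM is at least 15.2 counts.

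Before the data were examined, 37 gene lists (336 entries, 329 distinct genes, 315 of them in the file) were fixed, together with 7 questions, their tests, the alternatives and the rule for naming genes. A total of 35 lists had at least 3 measured members and were tested. The cell type lists cover dopamine, GABA, glutamate (vesicular glutamate transporter), serotonin, cholinergic or motor, interpeduncular or habenular, hypothalamic or mammillary and cortical or hippocampal neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial and mural cells, meningeal fibroblasts, ependyma, choroid plexus and erythrocytes. The other lists cover immediate early genes, glucocorticoid response, the circadian output or repressor arm and the activator arm, interferon response, MHC class II, nuclear-encoded oxidative phosphorylation, cytosolic ribosomal proteins, synaptic vesicle proteins, dopamine receptors, the opioid system, nicotinic receptors, the endocannabinoid system, orexin and corticotropin-releasing factor signalling, GABA-A receptors, ionotropic glutamate receptors and neuropeptides. Sex-linked genes were listed for description only. The rule names, per result, the 10 genes with the largest and the 10 with the most negative change that pass the test with the same direction in both identifier formats, the 10 most abundant genes, the 10 genes with the widest empty interval, and any member of a fixed list. The requirement of the same direction in both formats cannot be applied to a difference between the formats, for which only the adjusted p was used. Not every gene that meets the rule is named, and the checks on named slopes cover the named genes. Any other gene named was chosen after its values were seen.

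The spread of a list was the median over its members of the SD over libraries minus a lowess trend on mean expression. It was set against 10000 random lists of the same size, each member drawn from the 200 genes nearest in mean expression (two-sided). Co-expression was the mean pairwise Pearson r of the members against 10000 such random lists (one-sided, higher). A list score was the mean z-score of the members. Scores were related by Pearson r and Spearman rho with two-sided permutation p from 100000 resamples over the 591 pairs of lists with no shared gene, 32 of them with the dopamine neuron score, and r was given again without the 2 libraries farthest from the median of the first score. Genes were fitted with limma 3.58.1 (R 4.3.3), once on the standardised dopamine neuron score with identifier format as a covariate and once for hexadecimal minus decimal. A member of the dopamine list was tested against the score made without it. Lists were tested in these fits with camera, with a preset and with an estimated correlation. Correlation of neighbouring genes was the mean r of adjacent genes after removal of identifier format and 10 principal components, against 1000 permutations of gene order. Genes with separate clusters of animals were counted as those with an empty interval of at least 1 log2 unit and at least 5% of the libraries (8 of 152) on each side. This count has no test, and the count in normal draws with each gene's mean and SD was set beside it. All adjusted p are Benjamini-Hochberg at 0.05, over the genes, the lists or the pairs of the same family. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the rest.

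The limma fits, the tests of spread, co-expression, relations and neighbours and the count of intervals were tested on simulated data, and camera and the difference of relations between formats were not. For the difference between identifier formats, the limma fit recovered 78%, 92%, 100% and 100% of 50 genes each changed by 0.25, 0.5, 1 and 2 log2 units, and called 0.0782% of 15336 unchanged genes. For the dopamine neuron score it recovered 92%, 98%, 100% and 100%, and called 0.163% of unchanged genes. The spread and co-expression tests each found 5 of 5 altered lists and 0 of 28 unaltered ones. The relation test found 10 of 10 pairs with r of 0.4 and 1 of 5900 independent pairs. A simulated neighbour r of 0.05 was measured as 0.0504. The interval count found 200 of 200 genes with a step and 0 of 15336 without. In these simulations genes or scores varied independently apart from the changes put in, and the dopamine score was drawn at random. The rates of false calls therefore do not cover genes that vary together, as genes do in these data. Random splits of the real libraries with Th called up to 4160 genes, with a median of 0.

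The alternatives covered quantile normalization, a pseudocount of 0.1, other filters on low values, 1 identifier format at a time, other covariates and other thresholds. After the data were seen, further alternatives were added because 11 libraries had almost no transcripts of Th: every result was computed again without them, using a threshold of 10 CPM of Th, which leaves 141 libraries (140 with a decimal or hexadecimal identifier). Also added were the first principal component as a covariate and the removal of 1 of the 4 libraries with transcripts of both sexes, the relabelled one, which also held cortical transcripts. The thresholds for Xist (20 CPM), Ddx3y (5 CPM) and Slc17a7 (100 CPM) were likewise set after the data were seen, as were the tests on the libraries lacking Th, on libraries with transcripts of both sexes and on other splits. The first values given are those of the plan with 152 libraries, and the values for the 141 libraries stand beside them or lead where the 11 libraries would set the result. Transcripts of near-identical copies (pseudogenes, globin and MHC genes) are uncertain, because reads can be split between copies. The same may hold for uncharacterised LOC genes, for which copies were not looked for. No label says whether strand was used for overlapping genes.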

Results

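The transcriptome of the posterior ventral tegmental area was measured in outbred rats, with 15.2 to 57.2 M estimated counts per library (M stands for 1e6, mean 25.8 M, SD 7.68). Of the libraries 63 have a decimal and 88 a hexadecimal identifier and 1 another form. There are no treatment groups, so the questions concern how animals differ from one another. Each animal is represented by a dissected sample, and the share of a cell type in such a sample can differ. A difference between animals therefore cannot be told apart here from a difference in the tissue piece taken. Mbp, which encodes a main protein of central myelin, was the most abundant, with a mean of 14025 CPM (SD 4914, over all libraries). Also abundant were Zfp532, a zinc finger gene, with a mean of 6077 CPM that varied widely (SD 11077, highest 83157), and Scd2, a fatty acid desaturase gene, with 4820 CPM (SD 994). Others among the 10 most abundant genes were the myelin gene Mobp (3400 CPM), Zwint (3301), the astrocyte apolipoprotein gene Apoe (3176), Sparcl1 (2946) and 2 genes annotated as ribosomal RNA, LOC120093067 and LOC120099695, whose counts are uncertain because they are near-identical copies. The 20 most abundant genes held between 4.83% and 17.8% of a library's counts (median 7.88%), and ribosomal RNA genes 0.140% to 3.57% (median 0.980%).

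Dopamine neuron markers were abundant in most libraries and almost missing in 11. Th (chromosome 1, position 207508276), which encodes the rate-limiting enzyme of dopamine synthesis, lay between 577 and 3934 CPM in most libraries (53 decimal, 87 hexadecimal and 1 other, median 1820) and between 1.33 and 3.47 CPM in the other 11, with no library between. In the libraries with Th the median was 774 CPM for the dopamine transporter gene Slc6a3, 728 for the vesicular monoamine transporter gene Slc18a2, 493 for the decarboxylase gene Ddc and 157 for the midbrain transcription factor gene En1. In the 11 libraries Slc6a3 was at most 0.121 CPM and En1 at most 0.0412 CPM. The cortical glutamate transporter gene Slc17a7 had 1833 to 2040 CPM in the 11 libraries, against a median of 4.02 CPM in the libraries with Th. Neurod2, a transcription factor gene of forebrain neurons, was likewise high in the 11 (at least 88.4 CPM), and its highest value elsewhere was 51.2 CPM. Mbp was at most 2432 CPM in the 11 and at least 8524 CPM elsewhere. Of the 63 libraries with a decimal identifier 10 lack Th, and of the 88 with a hexadecimal identifier 1. Another 6 libraries have Th together with more than 100 CPM of Slc17a7, the highest being replicate 88 with 1064 CPM. The first 2 principal components held 32.0% and 21.4% of the variance over all libraries, and 31.9% and 11.2% over those with Th.

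**Figure D1:**
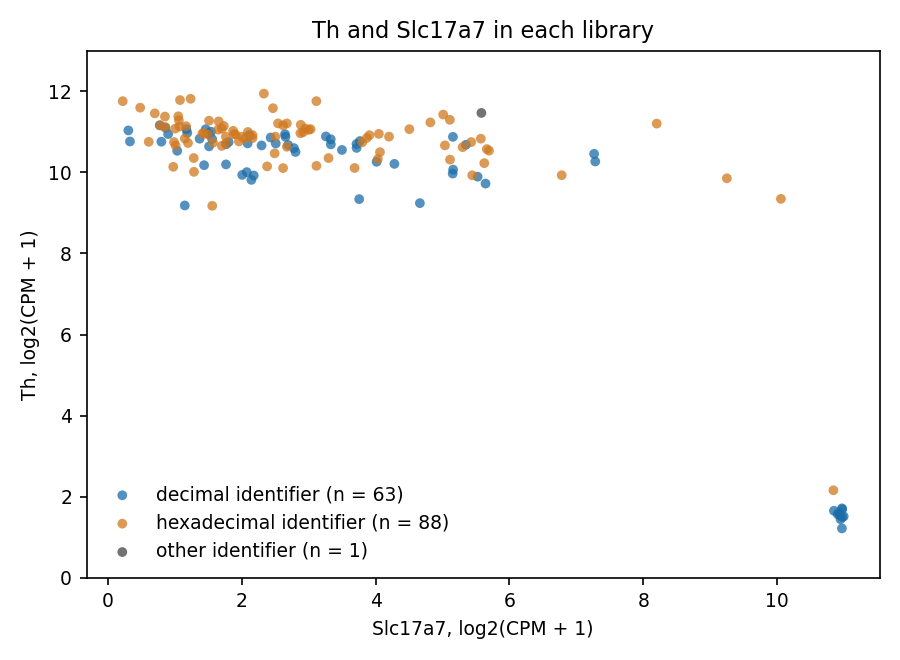
Th (y axis) against Slc17a7 (x axis) in each library, both in log2(CPM + 1), with 1 point per library coloured by identifier format. The 11 libraries with at most 3.47 CPM of Th stand at the lower right, with 1833 to 2040 CPM of Slc17a7.

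In the libraries with Th the lists that varied most between animals were those of meningeal fibroblasts, serotonin neurons and erythrocytes. The meningeal fibroblast list, led by the collagen gene Col1a1 (7.68 to 317 CPM, median 55.004, in the libraries with Th) and the growth factor gene Igf2 (19.9 to 2585 CPM, median 274), had a residual SD 0.96 log2 units above random lists over all libraries and 0.99 above in those with Th. The serotonin neuron list was 0.93 and 0.98 above, with the serotonin synthesis gene Tph2 between 0.124 and 160 CPM (median 2.07). The erythrocyte list was 0.83 and 0.81 above, with the globin gene Hba-a1 between 41.5 and 3046 CPM, a value that is uncertain because Hba-a2 is a near copy. The interpeduncular or habenular list was 0.98 and 0.57 above, with the nicotinic subunit gene Chrna2 between 0 and 113.7 CPM (median 23.7). The dopamine neuron list had the widest residual SD over all libraries, 1.43 above random lists. In the libraries with Th it stood 0.28 above (permutation, Benjamini-Hochberg adjusted p = 0.0007 and 0.000875).

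In all, 23 of 35 lists were wider than random lists over all libraries and 0 were narrower (permutation test, Benjamini-Hochberg). Unadjusted, 25 passed. Over the libraries with Th the number was again 23, of which 21 were the same lists. Wide in both, with the value for all libraries first and that for libraries with Th second, were cortical neurons (1.29, 0.32), the vesicular glutamate transporters (0.92, 0.39), nicotinic receptors (0.65, 0.43), immediate early genes (0.64, 0.16), neuropeptides (0.59, 0.39), the opioid system (0.52, 0.53), MHC class II (0.52, 0.56), choroid plexus (0.48, 0.28) and hypothalamic neurons (0.43, 0.35). Smaller excesses that passed in both were those of mural cells (0.33, 0.34), GABA neurons (0.29, 0.15), cholinergic neurons (0.29, 0.29), GABA-A receptors (0.29, 0.15), interferon response (0.28, 0.31), ionotropic glutamate receptors (0.26, 0.12) and glucocorticoid response (0.23, 0.26). Oligodendrocytes (0.59) and dopamine receptors (0.43) passed over all libraries and were at 0.05 and 0.19 over those with Th, without passing. Synaptic vesicle genes (0.08, 0.11) and nuclear oxidative phosphorylation genes (0.04, 0.08) passed over the libraries with Th only, and the difference between the sets of libraries was not tested. Not passing in either were ependyma (0.43, 0.26), orexin and corticotropin-releasing factor signalling (0.13, 0.13), astrocytes (0.11, 0.08), endothelium (0.10, 0.08), the circadian output arm (0.08, 0.06), the endocannabinoid system (0.07, -0.02), oligodendrocyte precursors (0.06, 0.04), the circadian activator arm (0.04, 0.04), microglia (0.02, 0.04) and ribosomal proteins (-0.05, -0.01). Within the libraries with Th, 24 lists passed for decimal and 23 for hexadecimal identifiers.

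Single genes with the widest residual SD in the libraries with Th were Xist (3.99 log2 units), the RNA of the inactive X chromosome, and the Y-linked genes Ddx3y (2.78) and Eif2s3y (2.68). They were followed by the beta-globin genes Hbbl1 (2.65) and Hbb-b2 (2.42), and by LOC134484082 (2.29), LOC134479241 (2.15), Ndrg3-ps1 (2.09), Rps14-ps7 (2.08) and LOC134485838 (2.04). Reads of these genes may be split between near copies, which was not tested for the LOC genes. LOC134484082 lies near Xist on X (positions 72531929 and 72558266). In decimal and hexadecimal libraries the residual SD was 0.74 and 2.47 for LOC134479241 and 0.19 and 2.27 for Rps14-ps7. For LOC134485838 it was 0.32 and 2.31. The other genes named here were wide in both formats. At the other end, Gid8, a subunit gene of a ubiquitin ligase, had an SD of only 0.06 log2 units (71.6 to 90.8 CPM), and the RNA demethylase gene Fto lay between 142.8 and 201.6 CPM. Srp68, a signal recognition particle gene, lay between 67.7 and 93.3 CPM, and Prkar1a, a regulatory subunit gene of protein kinase A, between 675 and 970 CPM. The others in the narrowest 10 were Gins4, Otud5, Rnf113a2, Cenpl, Pgap3 and Mapre2.

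For most cell types, the markers of the type rose and fell together from animal to animal. In the libraries with Th the mean pairwise r was 0.918 for meningeal fibroblast genes, 0.817 for erythrocyte genes, 0.775 for the nuclear genes of oxidative phosphorylation, 0.757 for interferon response genes and 0.7003 for dopamine neuron genes. Within the dopamine list, Slc18a2 (r = 0.972), Dlk1 (0.931) and the transporter gene Slc10a4 (0.915) tracked the other members most closely, and Slc6a3 had r = 0.597 (0.930 with a decimal and 0.560 with a hexadecimal identifier). Some hexadecimal libraries had much Th and little Slc6a3, for example replicates 70 (1977 and 38.2 CPM), 67 (2143 and 116.5) and 94 (2406 and 149.3), which were chosen after their values were seen. Serotonin neuron genes had a mean r of 0.65003, ependymal genes 0.615, ribosomal protein genes 0.611 and oligodendrocyte genes 0.566. The vesicular glutamate transporters did not move together (mean r = -0.135), and Slc17a6, the transporter of subcortical glutamate neurons, had r = -0.427 with the rest of its list.

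Over all libraries 27 of 35 lists exceeded random lists, and 26 of 35 did so over those with Th, 24 of them the same lists (permutation test, Benjamini-Hochberg, smallest possible p = 1e-04). The mean r over libraries with Th of the other lists that passed there was 0.491 for endothelium, 0.488 for nicotinic receptors, 0.469 for MHC class II, 0.452 for immediate early genes, 0.405 for interpeduncular neurons, 0.401 for choroid plexus, 0.392 for ionotropic glutamate receptors, 0.388 for microglia, 0.386 for cholinergic neurons, 0.359 for mural cells, 0.316 for GABA neurons, 0.306 for cortical neurons, 0.302 for the circadian output arm, 0.282 for glucocorticoid response, 0.265 for astrocytes, 0.263 for the opioid system and 0.262 for GABA-A receptors. Below the threshold were synaptic vesicle genes (0.144, adjusted p = 0.0574), oligodendrocyte precursors (0.143), the circadian activator arm (0.222), hypothalamic neurons (0.0903), neuropeptides (0.0756), endocannabinoid genes (0.0146), orexin and corticotropin-releasing factor signalling (-0.0516) and dopamine receptors (-0.103). With the 11 libraries included, the mean r was 0.952 for the dopamine list, 0.938 for oligodendrocytes and 0.852 for cortical neurons. Within the libraries with Th, the mean r of the dopamine list was 0.855 for decimal and 0.662 for hexadecimal identifiers, and 25 and 23 lists passed.

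Libraries with a higher dopamine neuron score had lower glutamate transporter scores and higher scores for orexin and corticotropin-releasing factor signalling, interpeduncular markers, neuropeptides and the opioid system. Members of the glutamate transporter, orexin and neuropeptide lists were not co-expressed beyond random lists, so these scores do not stand for each member. In the libraries with Th, the score of the vesicular glutamate transporters fell with the dopamine score (r = -0.563, rho = -0.577, r = -0.528 without the 2 farthest libraries). Orexin and corticotropin-releasing factor signalling rose with it (r = 0.516, rho = 0.442, 0.510 without 2), as did interpeduncular or habenular markers (r = 0.433, rho = 0.282, 0.389), neuropeptides (r = 0.429, rho = 0.324, 0.425) and the opioid system (r = 0.339, rho = 0.252, 0.347). The permutation p of r was 1e-05, the smallest possible, for the first 4 of these (Benjamini-Hochberg adjusted p = 4.44e-05) and 4e-05 for the opioid system (adjusted p = 0.000154). The p of rho was 1e-05 for the glutamate transporters and for orexin signalling, 0.00081 for interpeduncular markers, 5e-05 for neuropeptides and 0.00265 for the opioid system.

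In total 14 of 32 list scores were related to the dopamine score in the libraries with Th, 6 positively and 8 negatively, in a family of 591 pairs of which 292 passed. The remaining positive ones were synaptic vesicle genes (r = 0.248, rho = 0.249, 0.316 without 2, p = 0.00292, adjusted p = 0.00754) and ionotropic glutamate receptors (r = 0.239, rho = 0.209, 0.219, adjusted p = 0.0113). Nuclear oxidative phosphorylation genes (r = -0.328, rho = -0.352, -0.307, adjusted p = 0.000344), the circadian output arm (r = -0.3005, rho = -0.302, -0.285, adjusted p = 0.00071), the endocannabinoid system (r = -0.274, rho = -0.295, -0.263, adjusted p = 0.00318) and oligodendrocytes (r = -0.212, rho = -0.244, -0.265, adjusted p = 0.0252) fell with the score. For serotonin neurons (r = -0.303, adjusted p = 0.000657), endothelium (r = -0.221, adjusted p = 0.0192) and immediate early genes (r = -0.210, adjusted p = 0.0269) Pearson's r passed and Spearman's rho did not (rho = -0.149, -0.135 and -0.142, adjusted p = 0.128, 0.171 and 0.145). Without the 2 farthest libraries r was -0.264, -0.179 and -0.130 for these 3 lists.

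Scores that did not pass were those of choroid plexus (r = 0.193, adjusted p = 0.0507), GABA-A receptors (0.168), ependyma (0.144), meningeal fibroblasts (0.127), oligodendrocyte precursors (0.0813), ribosomal proteins (0.0453), the circadian activator arm (0.0160), hypothalamic neurons (0.00480) and interferon response (0.000251). On the negative side were microglia (r = -0.152), glucocorticoid response (-0.142), GABA neurons (-0.117), mural cells (-0.0980), astrocytes (-0.0860), cortical neurons (-0.0814), erythrocytes (-0.0612), cholinergic neurons (-0.0589) and MHC class II (-0.0447). Dopamine and nicotinic receptors share genes with the dopamine list and have no pair with it.

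Of the 32 relations, only those of orexin and corticotropin-releasing factor signalling and of synaptic vesicle genes passed a test of a difference between identifier formats. Their adjusted p was 0.00064 and 0.0349 (permutation of the formats). Below, the value for the 53 decimal libraries stands first and that for the 87 hexadecimal libraries second. For the glutamate transporters r was -0.443 and -0.623, for interpeduncular markers 0.495 and 0.442, for neuropeptides 0.477 and 0.393, for the opioid system 0.324 and 0.373, for oxidative phosphorylation -0.317 and -0.397 and for serotonin neurons -0.288 and -0.303. Orexin and corticotropin-releasing factor signalling had 0.837 and 0.260, and synaptic vesicle genes 0.701 and -0.0291. The remaining called lists had 0.248 and 0.302 (ionotropic glutamate receptors), -0.215 and -0.341 (circadian output arm), -0.155 and -0.324 (endocannabinoid system), -0.498 and -0.0833 (endothelium), -0.311 and -0.142 (oligodendrocytes), and -0.0952 and -0.323 (immediate early genes). With the 11 libraries included 30 of 32 relations passed, but these libraries form a separate cluster, so their pooled r is not given.

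**Figure D2:**
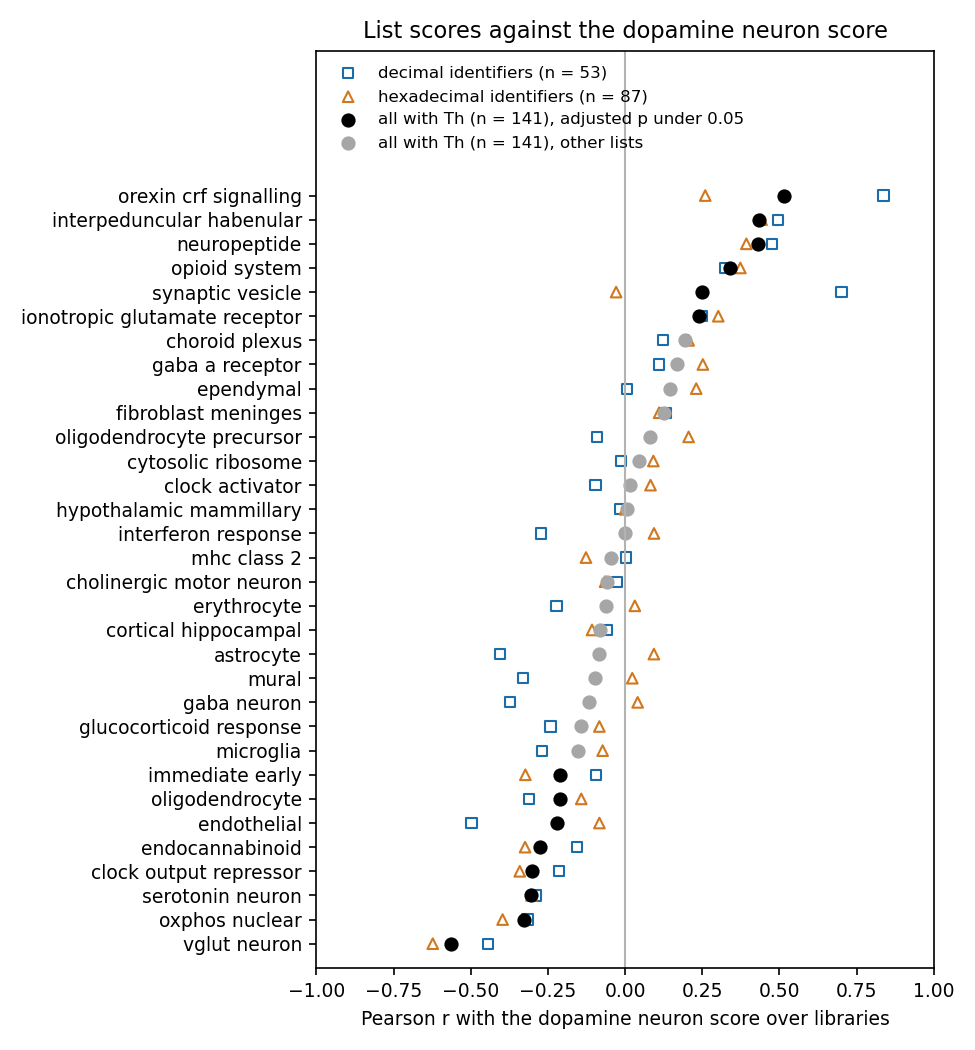
Pearson r of each list score with the dopamine neuron score over libraries with Th (x axis), for 32 lists (y axis). Circles stand for all libraries with Th (black for an adjusted p under 0.05), squares for the 53 with a decimal identifier and triangles for the 87 with a hexadecimal identifier, and the glutamate transporters lie lowest at -0.563.

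Genes that rose with the dopamine neuron score in the libraries with Th included transcripts of dopamine neurons. Grp, which encodes gastrin-releasing peptide, rose by 0.62 ± 0.04 log2 units per SD of the score (SE, n = 140, limma, Benjamini-Hochberg adjusted p = 1.12e-26). Slc6a3 rose by 0.56 ± 0.06 (adjusted p = 7.22e-15) and the nicotinic subunit gene Chrnb3 by 0.55 ± 0.03 (adjusted p = 1.39e-37) in the same limma fit. The largest fall was that of Slc17a7 (-0.89 ± 0.14, limma adjusted p = 4.36e-08), followed by Cartpt, the gene of the CART peptide (-0.88 ± 0.17, limma adjusted p = 6.95e-06).

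The other genes with the largest rise were Slc39a4, a zinc transporter gene (0.54), the secreted signal gene Wnt2 (0.54), Asb4 (0.53), the vesicle protein gene Sv2c (0.52), Tacr3, the neurokinin B receptor gene (0.52), Chrm5, a muscarinic receptor gene of dopamine neurons (0.52), and Gch1, whose enzyme makes the cofactor of Th (0.50). The other genes with the largest fall were the calcium-binding protein gene Cabp7 (-0.66), the sodium channel subunit gene Scn4b (-0.57), Neurod2 (-0.50), Arpp21 (-0.47), the osteopontin gene Spp1 (-0.47), the endothelial gene Plvap (-0.43), Lamp5 (-0.43) and the synaptotagmin gene Syt2 (-0.42). All of these had an adjusted p below 0.05 in limma. The mean of Neurod2 over all libraries was 1.13 log2 units, near the filter of 1, and its highest values lay in the libraries lacking Th. Its slope in the libraries with Th therefore rests on a gene of low expression there. In the 53 decimal libraries alone 5 of the falls did not pass (Cartpt, Scn4b, Spp1, Plvap and Syt2), Spp1 being at -0.17 (limma adjusted p = 0.530). With the first principal component added the slopes of Sv2c and Chrm5 were 0.29 and 0.31. Listed genes of dopamine neurons rose too: Th itself by 0.40 ± 0.03 against the score made without it, Slc18a2 by 0.46 ± 0.01, Ddc by 0.44 ± 0.02 and the autoreceptor gene Drd2 by 0.34 ± 0.02.

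In numbers, 5970 of 15536 genes passed in the 140 libraries with Th, 3469 of them rising and 2501 falling (limma, Benjamini-Hochberg). Over all libraries with a decimal or hexadecimal identifier 11505 genes passed, 7570 rising and 3935 falling, and 4604 genes passed in both. The share of rising genes was 65.8% over all these libraries and 53.1% after quantile normalization, and 58.1% and 48.7% over the 140. With the 11 libraries the steepest slopes were those of Slc6a3 (2.54 ± 0.06), Th (2.35 ± 0.04), Chrnb3 (2.00), Dlk1 (1.93), Chrna6 (1.90), En1 (1.88), Ret (1.81), Ddc (1.72), Slc10a4 (1.71) and Ebf3 (1.62). Among the most negative slopes were those of Slc17a7 (-2.31 ± 0.14), Tbr1 (-1.72), Kcnh3 (-1.69), Neurod2 (-1.67), Egr3 (-1.57), Ddn (-1.53), Mef2c (-1.40) and Chrm1 (-1.40). Without the 11 libraries the slopes of Kcnh3 (-0.15), Mef2c (-0.078), Chrm1 (-0.098) and Ddn (-0.078) no longer passed. The sign differed between all libraries and those with Th for Grp (-0.24 and 0.62), Cartpt (0.50 and -0.88), Scn4b (0.44 and -0.57), Spp1 (1.52 and -0.47), Plvap (0.37 and -0.43) and Syt2 (1.04 and -0.42), each passing in both.

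Nicotinic receptor genes, whose proteins answer to acetylcholine and nicotine, rose as a group. All 8 tested members rose with the score in the 140 libraries with Th, and all 8 did when adjusted over the list alone, among them Chrna5 (0.44), Chrna3 (0.37), Chrna2 (0.48) and Chrna4 (0.19). The list passed camera with an adjusted p of 2e-08, and with an estimated correlation at an adjusted p of 0.00855. With the first principal component added 6 rose (7 adjusted over the list alone), and the adjusted p was 4.24e-09, and 1.9e-05 with an estimated correlation. That fit also called a fall of endothelial genes, 9 of 9 (9 adjusted over the list alone, camera adjusted p = 0.000256), and of mural genes, 7 of 9 (8, adjusted p = 0.0352), with adjusted p of 0.243 and 0.289 with an estimated correlation. Of the 5 interpeduncular or habenular genes 4 rose (4 adjusted over the list alone), and all 4 are nicotinic subunits that the receptor list also holds. Its camera adjusted p was 0.0481, and the adjusted p was 0.573 with an estimated correlation. With the first component added 2 of the 5 rose (3 adjusted over the list alone, camera adjusted p = 0.0260, adjusted p = 0.307 with an estimated correlation), and the median slope of this list was 0.22 against 0.37 without it.

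Nuclear genes of oxidative phosphorylation fell as a group by small amounts. All 14 members fell, and 14 did adjusted over the list alone, including the cytochrome oxidase genes Cox7c (-0.13 ± 0.03) and Cox6c (-0.13 ± 0.03). The camera adjusted p was 6.23e-06, but the adjusted p was 0.573 with an estimated correlation. With the first principal component added 8 of the 14 fell (9 adjusted over the list alone, camera adjusted p = 0.0217, adjusted p = 0.529 with an estimated correlation), and the median slope of the list was -0.038 against -0.087 without it. Of 14 immediate early genes, which neurons switch on after activity, 8 fell and 1 rose (10 changed adjusted over the list alone). Among them were Arc (-0.28 ± 0.04), Egr1 (-0.17 ± 0.04) and Fos (-0.16 ± 0.04). This list had a camera adjusted p of 0.0443, and an adjusted p of 0.747 with an estimated correlation.

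Of 10 neuropeptide genes 4 rose and 1 fell (5 changed adjusted over the list alone), with rises in Cck, the cholecystokinin gene (0.37 ± 0.03), the neurotensin gene Nts (0.31 ± 0.05) and Adcyap1 (0.26 ± 0.03). Of 7 opioid genes 2 rose (2 adjusted over the list alone): the kappa receptor gene Oprk1 (0.36 ± 0.02) and its peptide ligand gene Pdyn (0.24 ± 0.04). With the first principal component added 2 opioid genes rose and 2 fell (4 adjusted over the list alone). The median slope of the list was then 0.020, against 0.061 without the component. Of 6 orexin and corticotropin-releasing factor genes 3 rose and 1 fell (5 changed adjusted over the list alone), namely Crhbp (0.32 ± 0.03) and the orexin receptor genes Hcrtr1 (0.12 ± 0.03) and Hcrtr2 (0.13 ± 0.03), and the receptor gene Crhr1 (-0.13 ± 0.03). All 3 tested serotonin genes fell (3 adjusted over the list alone), with Tph2 at -0.40 ± 0.11. None of these lists passed camera in the fit without further covariates. With the first principal component added the neuropeptide list passed (4 of 10 rose and 3 fell, 7 adjusted over the list alone, camera adjusted p = 0.0400), with an adjusted p of 0.289 with an estimated correlation. Over all libraries, those lacking Th included, camera called 11 lists. Among them were a fall of all 14 immediate early genes and of all 6 cortical genes and a rise of all 12 oligodendrocyte genes (14, 6 and 12 adjusted over the list alone). Of these lists only the nicotinic, interpeduncular and immediate early ones also passed in the libraries with Th. There 3 oligodendrocyte genes fell and 0 rose (2 changed adjusted over the list alone, camera adjusted p = 0.0767). The camera adjusted p there was 0.527 for cortical and 0.323 for endocannabinoid genes. Over all libraries, the cortical and endocannabinoid lists kept an adjusted p of 0.0199 each with an estimated correlation and the immediate early genes an adjusted p of 0.04998. The call was lost, with an estimated correlation, for oligodendrocytes, synaptic vesicle genes, nicotinic receptors and GABA-A receptors (adjusted p = 0.171 each), the circadian activator arm (0.172), interpeduncular markers (0.1999), the circadian output arm (0.248) and ionotropic glutamate receptors (0.567).

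Libraries with a hexadecimal identifier differed from those with a decimal one in many genes by small amounts. Among genes of known function Adcy1, an adenylyl cyclase gene, was lower with a hexadecimal identifier by a log2 difference of -1.13 ± 0.21 over all libraries and -0.77 ± 0.19 over the 140 with Th (limma, Benjamini-Hochberg adjusted p = 7.17e-06 and 0.00103), and of -0.33 there with the first principal component added (limma adjusted p = 0.0188). Th was higher by 1.66 ± 0.38 over all libraries and by 0.33 ± 0.09 over 140 (limma adjusted p = 0.000166 and 0.00172). Dlk1 (1.28 and 0.23), En1 (1.27 and 0.23) and Slc10a4 (1.19 and 0.26) were higher in both as well, and with the first component added En1 (0.15) did not pass. The identifier format is not a group of the study, and 10 of the 11 libraries lacking Th have a decimal identifier.

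The largest differences lay mostly in uncharacterised LOC genes, pseudogenes and genes named as copies. Their reads may be split between near copies, which was not tested. Higher with a hexadecimal identifier were LOC134486537 (2.14 over all libraries, 2.16 over those with Th), LOC134485838 (2.04, 2.09), LOC134479241 (1.89, 1.86), Cox7a2l2 (1.35, 1.33) and the ribosomal RNA precursor gene Rn45s (1.31, 1.47). Lower were Rps14-ps7 (-2.22, -2.24), Rplp2l2 (-1.25, -1.37) and Hmgb1l2 (-1.04, -1.02). LOC134485838, LOC134479241 and Rps14-ps7 varied widely mainly within the hexadecimal libraries, so their mean difference does not describe each library. For Slc6a3 the difference was 1.20 over all libraries and -0.20 over those with Th (adjusted p = 0.311, limma), and for Slc17a7 -1.13 and 0.080 (adjusted p = 0.867, limma). The remaining lower genes of the 10 over all libraries were Kcnh3 (-1.10, -0.13), Hbbl1 (-1.06, -1.07), Egr3 (-1.03, -0.13), Tbr1 (-1.01, -0.023) and Kcnf1 (-0.9985, -0.37), of which Kcnf1 passed over 140 libraries and the other 4 did not. Over 140 libraries Cartpt (-0.98), Dzank1 (-0.87) and Hsp90aa1-ps17 (0.98) were also among the 10 largest in their direction, and the rest were LOC genes. With the first principal component added the differences of LOC134486537, LOC134485838 and LOC134479241 were 1.19, 1.23 and 0.94, those of Cartpt and Dzank1 -1.43 and -0.45, and Hsp90aa1-ps17 (0.48, limma adjusted p = 0.0505) and 2 LOC genes did not pass. Kcnf1 (-0.11) did not pass there either.

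Over all libraries with a decimal or hexadecimal identifier 7657 of 15536 genes passed (3740 higher and 3917 lower with a hexadecimal identifier), 338 of them by at least 0.5 log2 units (limma, Benjamini-Hochberg). Over 140 libraries 5904 passed (2217 and 3687), the number by at least 0.5 being 44.97% of that over all libraries, and 4329 genes passed in both. The share of genes higher with a hexadecimal identifier was 37.6% over the 140 libraries, 46.8% there after quantile normalization and 53.5% with the first principal component added. Quantile normalization left an excess of lower genes (by at least 0.5, 33 higher and the others lower), and the first component turned it (65 higher and 14 lower). Of 14 nuclear oxidative phosphorylation genes 10 were higher over all libraries and 8 over 140 (11 and 9 adjusted over the list alone). The camera adjusted p for this list was 0.00535 and 0.00776, and the adjusted p was 0.907 and 0.997 with an estimated correlation. Camera also called 5 lists over all libraries alone, each with an adjusted p of 0.907 with an estimated correlation: cortical neurons (6 of 6 lower, 6 adjusted over the list alone), oligodendrocytes (10 of 12 higher, 11), MHC class II (5 of 7 higher, 7), GABA-A receptors (11 of 11 lower, 11) and ionotropic glutamate receptors (9 of 14 lower and 1 higher, 10).

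Genes next to each other on a chromosome were expressed more alike than genes apart. The X-linked genes Gprasp1 and Gprasp2 encode proteins that sort receptors and lie 52.8 kb apart. Their r was 0.883 over the libraries with Th (0.858 with a decimal and 0.929 with a hexadecimal identifier). Their symbols are alike, so this pair is among those left out in the test without tandem copies. Y-linked pairs were among the highest too (Kdm5d and Eif2s3y, r = 0.912, Uty and Ddx3y, r = 0.857), and sex was not a covariate. Opposite pairs existed too: Acad9, a mitochondrial enzyme gene, and Zfp267 had r = -0.701 (-0.718 and -0.705), the purine synthesis gene Atic and the fibronectin gene Fn1 r = -0.611, Bcr and Rab36 r = -0.605, and Ccs and Ctsf r = -0.581. The highest pairs also held globin genes (Hba-a2 and Hba-a1, r = 0.989, Hbb-bs and Hbb-b1, r = 0.915) and the lowest Hbbl1 and Hbb-b2 (r = -0.826) and MHC or histone copies (RT1-A3 and RT1-A2, r = -0.667, Hist2h2aa2 and H2ac18, r = -0.747), all uncertain because of near-identical copies. These pairs were picked from all pairs after their values were seen, and genes are not independent replicates.

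Over all libraries the mean r of 15514 adjacent pairs was 0.0569, against a mean of 0.0136 and a highest value of 0.0166 in 1000 permuted gene orders (two-sided permutation p = 0.002, the smallest possible). Over the libraries with Th it was 0.0536, with 0.0537 for decimal and 0.0529 for hexadecimal identifiers. The mean fell with the number of genes between, from 0.0364 for genes 2 apart to 0.0246 for genes 10 apart and 0.0148 for genes 100 apart. By distance between adjacent genes it did not fall steadily: it was 0.0585 at 1 kb or less, 0.0845 at 1 to 10 kb, 0.0557 at 10 to 100 kb, 0.0418 at 100 kb to 1 Mb and 0.0444 over 1 Mb. Pairs read from 1 strand had 0.0560, divergent pairs 0.0520 and convergent pairs 0.0512. Over all libraries 6.95% of adjacent pairs had r above 0.3 and 1.22% below -0.3. The mean was 0.125 without the removal of principal components (permuted mean 0.0488) and 0.0289 with 30 removed.

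**Figure D3:**
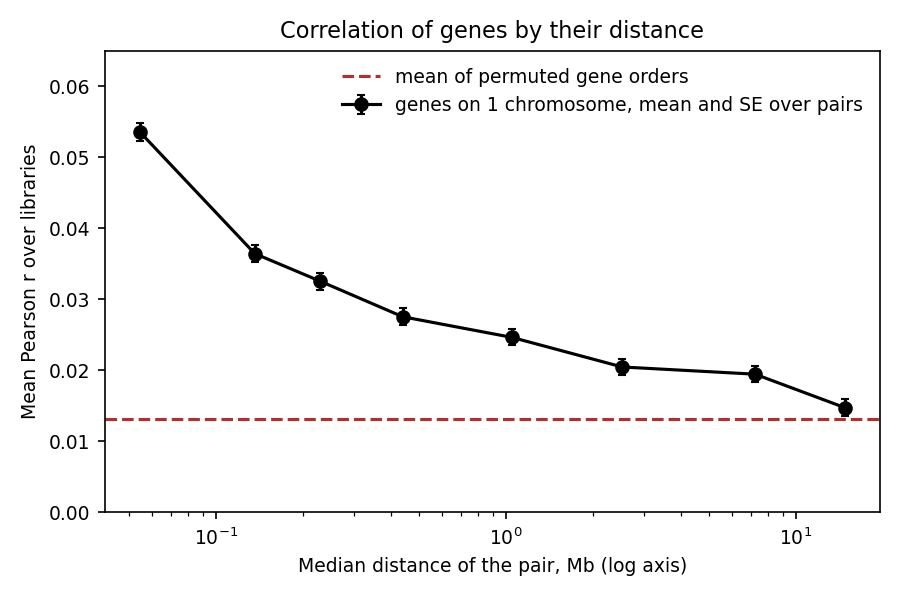
Mean Pearson r over the libraries with Th of genes on 1 chromosome that are 1, 2, 3, 5, 10, 20, 50 or 100 genes apart (y axis) against the median distance of the pair in Mb (log x axis). Points are means, bars the SE over pairs, which are not independent, and the dashed line is the mean of permuted gene orders, and the mean r lies between 0.0536 for adjacent genes and 0.0148 for genes 100 apart.

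Expression of some genes fell into separate ranges with no animal between. In the libraries with Th the widest empty intervals were those of sex-linked genes: Eif2s3y (4.69 log2 units), Ddx3y (4.197), Xist (3.96) and Kdm5d (3.34). Among autosomal genes the widest was that of Fam111a, a protease gene with a part in DNA replication (chromosome 1, position 219065542). It lay at 0.772 CPM or less in 79 libraries and at 10.1 CPM or more in 62. Next came LOC120101770 (2.29), Ndrg3-ps1 (2.09), Rpl30l2 (2.07), the Y-linked LOC103694537 (1.73) and Hbb-b2 (1.56). Reads of these genes may be split between near copies, which was not tested. The MHC class I gene RT1-CE16 had an interval of 1.35, with 49 libraries below and 92 above, and Lrrc71, a gene of a leucine-rich repeat protein, one of 1.01 (12 libraries above). RT1-CE16 and Lrrc71 lie outside the 10 widest and were chosen after their values were seen.

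Over all libraries 523 genes had such an interval, 496 of them on autosomes, 22 on X and 5 of the 6 tested genes on Y, while normal draws gave a mean of 0.1 genes. Without the 11 libraries lacking Th 21 genes had one (13 on autosomes, 3 on X and 5 on Y), 19 of them among the 523. With all libraries the widest intervals were those of dopamine genes: Th (7.02), Dlk1 (5.46), Slc6a3 (5.13), En1 (5.12), Ret (4.82), Chrnb3 (4.71), Slc10a4 (4.65), Ddc (4.51) and Slc18a2 (4.26), with Eif2s3y (4.69) among them. The lower side of 57 of the 523 genes lay below 1 CPM. The count has no test, and no animals were grouped by it.

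**Figure D4:**
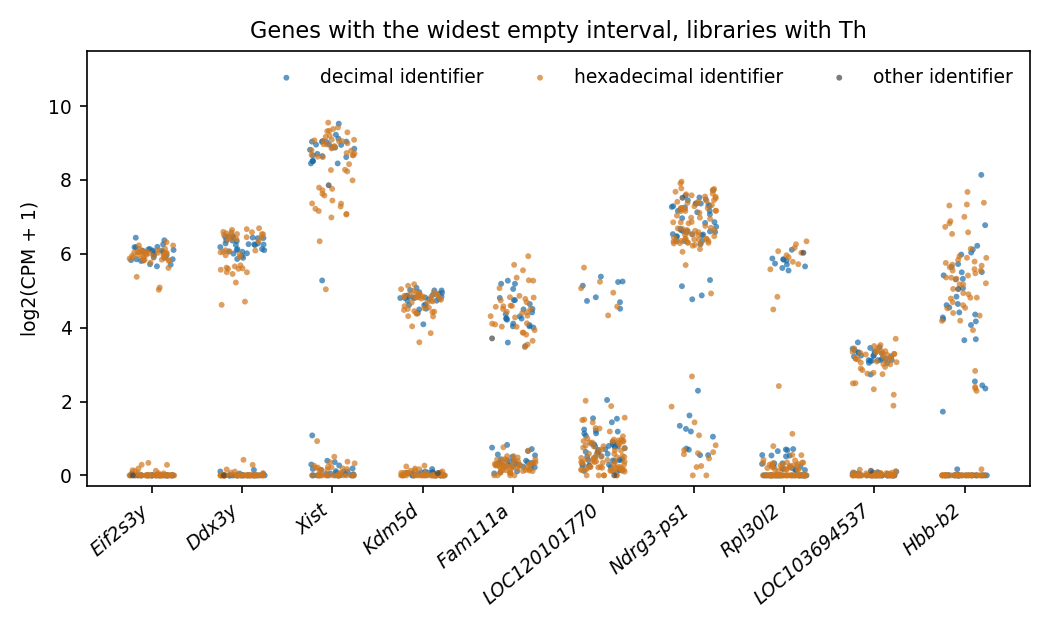
Expression in log2(CPM + 1) (y axis) of the 10 genes with the widest empty interval in the libraries with Th, with 1 point per library coloured by identifier format. Fam111a lies at 0.772 CPM or less in 79 libraries and at 10.1 CPM or more in 62.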

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

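The tests of a difference between identifier formats in this part were run on the libraries with Th, and that choice and the tests on other splits were made after the first results were seen.

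The relation of synaptic vesicle genes to the dopamine neuron score stood out because it differed between the identifier formats: r was 0.701 in 53 decimal and -0.0291 in 87 hexadecimal libraries, a difference in Fisher z of -0.90 (permutation of the formats, adjusted p = 0.0349 over 32 lists). It was 0.655 and 0.0720 without the 2 farthest libraries of each. Spearman's rho was 0.471 and 0.0928, a smaller difference that was not tested. The relation of orexin and corticotropin-releasing factor signalling differed in the same way, with r of 0.837 and 0.260 (0.796 and 0.231 without 2), a difference in Fisher z of -0.95 (adjusted p = 0.00064). Its rho was 0.731 and 0.251. For the slope of single genes on the dopamine neuron score 1 of 15536 genes differed between the formats (limma, Benjamini-Hochberg), against 2414 at an unadjusted p under 0.05. This gene is Tmem178a, with slopes of -0.041 (decimal) and -0.27 (hexadecimal) and a difference of -0.24 (limma adjusted p = 0.0359). No explanation for these 3 values was tested.

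Over all libraries with a decimal or hexadecimal identifier, more genes differed between the identifier formats than in random splits. In the real split 7657 passed and in the others 1659 at most, so 1 of 100 splits, the real one, gave as many. As 1 of 100 is the smallest share possible here, this argues against chance but does not exclude it. Over the 140 libraries with Th the real split gave 5904 genes and the highest other split 4160, and again 1 of 100 splits gave as many. The cause of the 4160 genes in that other split was not tested.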

How the results depend on the processing

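Alternatives without the libraries lacking Th, with the first principal component or without the mixed library (1 of the 4 with transcripts of both sexes, the other 3 kept) were chosen after seeing the data, and the others before. The word mixed is a short name for this library, and a mixture was not shown. Replicates 38 and 40 were kept, although their median shares of the genes high in the libraries lacking Th were 10.9% and 7.69%.

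The count of wide lists lay between 14 and 25 under the alternatives, the lowest being 14 of 27 with genes of mean at least 3, where fewer lists could be tested. The count of co-expressed lists lay between 22 and 31. The mean r of neighbours lay between 0.0289 and 0.125, above every permuted order in all 10 alternatives. Of 32 relations with the dopamine score, 30 passed over all libraries and 16 in hexadecimal libraries only. Without the libraries lacking Th, 14 passed, and then 15 with quantile normalization, 15 with a pseudocount of 0.1, 9 in decimal and 11 in hexadecimal libraries only, 14 without recovered libraries, 14 with markers of mean at least 3, 15 with identifier format removed, 18 with the first principal component removed too and 14 without the mixed library. Of the 18 with the first principal component removed, 5 were positive and 13 negative, against 6 and 8 of the 14. Within the 11 libraries lacking Th 0 passed, where few libraries enter. In the checks on the 14 relations 15 lost the call. For synaptic vesicle genes in hexadecimal libraries r was 0.0322 with scores made within these libraries and -0.0291 with scores made over both formats.

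Genes related to the dopamine score numbered 11505, but 6232 with oligodendrocyte and astrocyte scores added and 3834 in hexadecimal libraries only. Without the libraries lacking Th they numbered 5970, and then 2675 in decimal and 4752 in hexadecimal libraries only, 5734 with the first component added, 5923 without the mixed library and 5937 with quantile normalization. Genes differing between identifier formats numbered 4232 to 7915, the lowest without the libraries lacking Th and with the first component added. Those differing by at least 0.5 numbered 338. As a percentage of that count they were 176.6% with a pseudocount of 0.1, 50.9% with 3 cell type scores added, 44.97% without the libraries lacking Th, and then 40.8% with quantile normalization and 23.4% with the first component. Genes with separate clusters numbered 523. As a percentage of that count they were 241.7% with an interval of 0.5, 23.9% with 2 and 3.44% with at least 10% on each side. Without the libraries lacking Th they were 4.02%, and then 8.80% with an interval of 0.5, 3.25% with at least 10%, 3.82% with quantile normalization, 8.03% with a pseudocount of 0.1, 4.21% without the mixed library, 7.84% in decimal and 5.54% in hexadecimal libraries only.

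All planned checks of 18 named slopes kept direction and call. Of the added ones 81 kept both, 27 lost the call and 0 reversed. Of 173 checks of 20 differences between formats 21 lost the call and 7 reversed, and of 40 checks of the differences without the libraries lacking Th 3 lost it. The difference of Slc6a3 was -0.28 with 3 cell type scores added, -0.20 without the libraries lacking Th and -0.22 then with quantile normalization. That of Slc17a7 was 0.26, 0.080 and 0.089 in these settings and 0.082 with the first component added. The cause of these changes was not tested beyond the libraries left out. No paired analysis was possible because the labels give 1 group and replicate numbers that are names only.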

Other observations

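Tests in this part on the libraries lacking Th and on libraries with both Xist and Y-linked transcripts were chosen after the first results were seen, as was the neighbour test without the libraries lacking Th. The neighbour test without overlapping genes was planned, and that without tandem copies was written down before its result was seen.

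Vascular and border cells varied together across the libraries with Th. The endothelial score rose with the mural score (r = 0.852, rho = 0.847, 0.847 without the 2 farthest libraries), the mural with the meningeal fibroblast score (r = 0.798, rho = 0.817, 0.793), and the fibroblast score with MHC class II genes, which present antigen (r = 0.761, rho = 0.737, 0.741). Nuclear oxidative phosphorylation genes fell as ionotropic glutamate receptors rose (r = -0.845, rho = -0.754, -0.843), and astrocyte markers fell as synaptic vesicle genes rose (r = -0.635, rho = -0.653, -0.621). Interpeduncular markers and the opioid system rose together (r = 0.784, rho = 0.818, 0.768). All 6 had a permutation p of 1e-05, the smallest possible, and a Benjamini-Hochberg adjusted p of 4.44e-05 among 591 pairs. The 2 arms of the circadian clock went opposite ways (r = -0.272, rho = -0.275, -0.273, adjusted p = 0.00314).

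Some genes were high in a minority of libraries, and the source of these transcripts was not tested. Tph2 exceeded 10 CPM in 16 libraries and reached 160 CPM, the choroid plexus gene Ttr exceeded 100 CPM in 1 library, where it had 11987 CPM, and the pituitary hormone precursor gene Pomc reached 1353 CPM against a median of 1.85. Among libraries, 79 held Xist alone, 69 the Y-linked gene Ddx3y alone and 4 both.

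The absence of Th from 11 libraries has a candidate explanation in cortical tissue that carries this region's label, through a wrong label or an exchange with a sample from outside the series. All 6 measured cortical or hippocampal markers lay higher in each of the 11 than in every other library, 6 of 6, and the dopamine neuron markers had a median of 0.61% of their usual level. A mixture with 10% or more of this region is argued against by the 15 dopamine neuron markers other than Th, which defined the 11: their median level per library was at most 0.772% of that elsewhere. Low depth is argued against too, since their median total of 24.8 M (1e6 estimated counts) lies above the lower quartile of the others (20.3 M). No biological explanation was tested, because the labels give no second region or group.

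The 4 libraries with both Xist and Y-linked transcripts may hold RNA or reads of 2 animals of different sex. Relative to libraries with only 1 of the 2, Xist was at 8.23%, 37.7%, 6.94% and 29.3% and the Y-linked genes at 100.7%, 55.5%, 93.2% and 47.1%. The sums of these shares were 1.09 at most and 0.763 at least, which does not by itself mark a mixture, since libraries with only 1 of the 2 ranged from 80.1 to 964 CPM of Xist and from 23.6 to 102.4 CPM of Ddx3y. The last of the 4, a relabelled library, had 293 CPM of Slc17a7 beside 2357 CPM of Th, and 85.1% of the genes at least 10 times higher in the libraries lacking Th had a share within 1.5 times of their median of 12.6% (median of the 140 other libraries with Th -0.0281%, highest 10.9% in replicate 38), in line with a share of a cortical library. Replicate 40, which does not hold both, met the same criterion (76.3% of the genes, share 7.69%), so this pattern does not single out the libraries with both, and a sex chromosome variant in these animals was not tested.

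The correlation of neighbouring genes could come from reads shared by overlapping genes, but without these the mean r was 0.0559, above the highest of 1000 permuted orders (0.0167). Tandem copies of related genes are argued against as the whole cause, since 11411 pairs without like symbols, LOC genes and overlap had a mean r of 0.0501 (highest permuted 0.0172). The libraries lacking Th are not the cause either, since the mean r without them was 0.0536 (highest permuted 0.0167). Regulation by shared founder haplotypes remains open, and no biological explanation was tested, because genotypes were not used here.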
